A study of Mus musculus with 8 samples.

How the data were processed

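Testes of juvenile C57BL/6 mice were profiled on 8 Agilent whole-genome expression arrays, each hybridised with 1 Cy3-labelled RNA sample. Per the labels, littermates with 2 intact copies of Ip6k1 (wild type) and littermates lacking both copies (knockout) came from crosses of heterozygotes and were killed at 17 or at 26 dpp (days postpartum). This gives 4 groups of 2 arrays, and the labels call the 2 arrays of a group biological replicates. Per the labels' protocols, RNA was extracted with TRIZOL, reverse transcribed from an oligo-dT primer and transcribed into Cy3-labelled cRNA. The part of Ip6k1 removed by the knockout allele, and the strain in which the allele was made, are not given in the sources used here.

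Spot brightness was read per array with Agilent Feature Extraction, named in the submitters' processing notes and given as version 11.5.1.1 per the file headers. The processed signal, the mean signal and the local background signal are intensity values on a linear scale, deposited per array without scaling between arrays; the processed signal is corrected for background and spatial trend, per the file headers. Other columns of the deposited scanner files hold flags, of which those for control spots, for spots well above background and for outlier spots were used. The authors' value table holds log2 values, and no header or label states their scale, centring or direction. Set against the same arrays, each deposited column followed log2 of the processed signal with a correlation of 0.999906 to 0.999946 across probes and lay near it minus the array's 75th percentile, with no centring per probe. This leaves neither scale nor centring open, and a 1-colour value has no direction; how spots of one probe were combined stays unknown. Medians of the deposited columns were −3.69 and −3.69 for wild type at 17 dpp, −3.67 and −3.63 for knockout at 17 dpp, −3.59 and −3.65 for wild type at 26 dpp, and −3.62 and −3.84 for knockout at 26 dpp. Probe coordinates are those of the files, on mm9. No reference genome was used here, so no exon or UTR is assigned to a probe.

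Each array held 59305 non-control spots of 55681 probes, 432 of them with several spots. Outlier spots (103 to 200 per array) were left out, no spot was saturated (0 on every array), and spots of one probe were averaged. The 75th percentile of the processed signal was 512 and 503 in wild type at 17 dpp, 520 and 470 in knockout at 17 dpp, 637 and 666 in wild type at 26 dpp, and 692 and 485 in knockout at 26 dpp. The values analysed are log2 of the processed signal minus log2 of that percentile. A probe was kept when well above background on both arrays of at least 1 group. Of the probes that met this rule, 94 were left out because an outlier flag left an array without a value, and 37807 remained. A gene was represented by its kept probe with the highest mean signal over all 8 arrays, giving 26584 genes, of which 7487 had more than 1 kept probe. Accessions gave a current symbol to 27516 probes, 3547 more carried a current symbol in the files, and 24618 kept the name in the file. Of the genes tested, 18192 had a current symbol and 3411 were long intergenic non-coding RNA (lincRNA) probes.

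Differences were tested with limma 3.58.1 in R 4.3.3, with data.table, version 1.17.8, for reading the files. The model had 1 mean per group, fitted over all 8 arrays, with default empirical Bayes moderation and two-sided tests. The fit had 4 residual degrees of freedom and a prior worth 2.05 more. P-values were adjusted by Benjamini-Hochberg over the 26584 genes, and an adjusted p under 0.05 counted as passed. Counts at an unadjusted p under 0.05 are also given. If no gene changed, a calibrated test would place a share of about 0.05 of the genes there. In the knockout comparisons with all arrays the counts lay below that share, so they are no sign of missed effects. With so cautious a test, 0 called genes are no sign of absent effects either. The 6 comparisons were knockout against wild type at 17 dpp, at 26 dpp and averaged over both ages, the difference between those effects, and 26 against 17 dpp in each genotype. In addition, 24 gene lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison. The lists cover inositol phosphate kinases and phosphatases, 6 stages or functions of germ cells, Sertoli, Leydig, peritubular myoid, macrophage, endothelial, red blood, epididymis and adipocyte markers, and 9 pathways. An estimated correlation and limma's fry, which asks whether a list's genes move on balance one way, served as alternatives. For a gene not well above background in a whole group the fold is given as "at least": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

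The groups, the tests, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule names, per comparison, up to 10 genes per direction with the largest change among those that passed and whose groups do not overlap, then those with the smallest p among genes changed at least 2-fold, and up to 4 members of each list; predicted and unnamed genes are not eligible. The alternatives were quantile normalization, normexp background correction with quantile or 75th percentile scaling, no or a stricter filter on dim probes, other ways to combine probes, other variance models, other thresholds, the authors' deposited log2 values, the replicate number as a block, and leaving out each array in turn.

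The steps were tested on simulated data made from the arrays' own means and spread for the comparison at 17 dpp. The simulated noise was independent between genes and had the same spread per gene in all groups, taken over all arrays of the fit. In the real arrays the knockout replicates at 26 dpp differed most (correlation 0.863), so the shares below need not hold for the real comparison. With 200 of 26584 genes changed, 0%, 30%, 70% and 88% of those changed by 1, 2, 4 and 8 on the log2 scale were called, with 3 unchanged genes called. Without knockout replicate 2 at 26 dpp these shares were 8%, 56%, 78% and 94%, with 4 unchanged genes called. The number of arrays, 2 per group, limits the precision. All arrays lay on 1 slide with 1 scan time in the headers, so there was no slide or scan batch to test; the position on the slide went with age and cannot be separated from it.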

Results

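Gene expression was measured in testes of wild type and Ip6k1 knockout mice at 17 and at 26 dpp, with 2 arrays per group (n = 2), called biological replicates in the labels. Ip6k1 encodes inositol hexakisphosphate kinase 1, which makes an inositol pyrophosphate. Between these ages the first wave of mouse spermatogenesis passes from spermatocytes to spermatids. Values are log2 signals relative to each array's 75th percentile. The share of probes well above background was 63.3% and 64.6% in wild type and 62.7% and 63.7% in knockout at 17 dpp. At 26 dpp it was 62.8% and 62.1% in wild type and 64.2% and 58.8% in knockout. Replicates correlated across genes, which are not independent replicates, at 0.989 in wild type and 0.980 in knockout at 17 dpp, at 0.987 in wild type at 26 dpp and at 0.863 in knockout at 26 dpp. Knockout replicate 2 at 26 dpp stood apart. It correlated at 0.917 to 0.948 with the arrays of 17 dpp and at 0.873 and 0.838 with wild type at 26 dpp, where knockout replicate 1 reached 0.992 and 0.989. Its median log2 signal of spike-in probes, 11.025, lay with the arrays of 17 dpp (10.505 to 11.02) and above the other arrays of 26 dpp (9.41 to 9.88).

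The targeted gene was lower in all 4 knockout arrays than in all 4 wild type arrays. The Ip6k1 probe, spotted 10 times (chromosome 9, 107950832 to 107950891), read 2.25 ± 0.075 (SD, n = 2) in wild type and 1.43 ± 0.09 in knockout at 17 dpp. At 26 dpp it read 2.78 ± 0.02 and 1.35 ± 0.081. The difference was −0.82 (SE 0.215) at 17 dpp and −1.43 (SE 0.215) at 26 dpp, larger than the spread between replicates. It did not pass over all genes in limma, with an adjusted p of 1 and 0.527, and 0.195 for the average of −1.12. Ip6k1 did pass at 26 dpp and in the average as 1 of 20 measured inositol phosphate kinases and phosphatases when adjusted over the list alone. Over the alternatives its adjusted p at 26 dpp ranged from 0.00419, without knockout replicate 1 at 26 dpp, to 0.891. The probe stayed well above background in every knockout array. The labels do not say which part of the gene was deleted, and a probe outside that part checks nothing about the genotype. The paralogue Ip6k2 (chromosome 9, 108698667 to 108698726) read −0.80 in wild type and −1.07 in knockout at 17 dpp, and −1.93 and −1.61 at 26 dpp. Ip6k3 was not well above background on any array.

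Near Ip6k1 on chromosome 9, Amigo3, Hyal3 and Traip were higher in all 4 knockout arrays without passing over all genes. Traip (107873796 to 107873855) differed by 1.20 at 17 dpp and by 0.615 at 26 dpp, with a limma adjusted p of 0.833 for the average of 0.91. Rhoa (108239660 to 108239719) was lower in all 4, by −0.13 on average (limma adjusted p = 0.833). Traip and Rhoa were picked after their values were seen. Amigo3, which encodes a transmembrane cell adhesion protein (107957685 to 107957744), differed by 2.23 at 17 dpp (SE 0.299, adjusted p = 0.184) and by 2.06 at 26 dpp (SE 0.299, adjusted p = 0.493). Hyal3, of the hyaluronidase family (107489520 to 107489579), was not well above background in wild type and was at least 1.74-fold higher in knockout at 17 dpp and at least 1.13-fold at 26 dpp, where 1 of 2 knockout arrays measured it (adjusted p = 1 and 0.535). Gmppb (107953830 to 107953889) and Rnf123 (107954225 to 107954284), whose probes lie between those of Ip6k1 and Amigo3, differed by −0.14 and −0.20 on average, with adjusted p of 0.84 and 0.833. Both were chosen for their position after their values were seen. Without knockout replicate 2 at 26 dpp the average log2 difference of Gmppb was 0.0268.

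**Figure D1:**
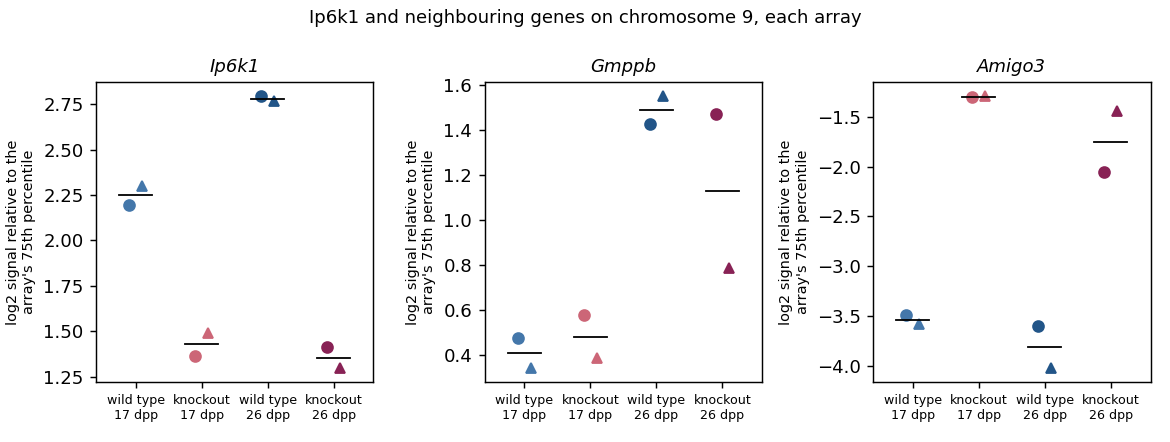
Log2 signal relative to each array's 75th percentile (vertical axis) of Ip6k1, Gmppb and Amigo3 in each of the 8 arrays by group; circles are replicate 1, triangles replicate 2 and horizontal lines group means. Ip6k1 lies at 1.30 to 1.49 in the knockout arrays and at 2.20 to 2.80 in wild type, and Amigo3 at −2.06 to −1.29 in knockout and at −4.02 to −3.49 in wild type.

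At 17 dpp, 3 members of the fixed list of epididymis markers fell in knockout. Crisp1, a cysteine-rich secretory protein, read 1.77 ± 1.135 (SD, n = 2) in wild type, was not well above background in either knockout array and was at least 156-fold lower (adjusted p = 0.0317). Adam7, a membrane protein of epididymal epithelium, and Rnase9, of the ribonuclease A family, were at least 45.9-fold and 2.93-fold lower (adjusted p = 0.0317 each). The other genes named here are in none of the fixed lists. For the listed markers and these genes alike, the design does not separate a knockout effect from epididymal tissue carried over in wild type, taken up below. Crisp3, also a cysteine-rich secretory protein, read 4.66 ± 1.075 (SD, n = 2) in wild type and was at least 1150-fold lower (adjusted p = 0.0368). The beta-defensins Defb2, Defb23, Defb37, Defb38 and Defb40 were at least 92.1-, 20.5-, 13.6-, 13.5- and 9.99-fold lower. Rnase12, of the ribonuclease A family, was at least 176-fold lower and the protease inhibitor gene Wfdc15b at least 170-fold. The neuropeptide gene Npy and Iapp, which encodes islet amyloid polypeptide, were at least 16.2-fold and 4.36-fold lower.

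**Figure D2:**
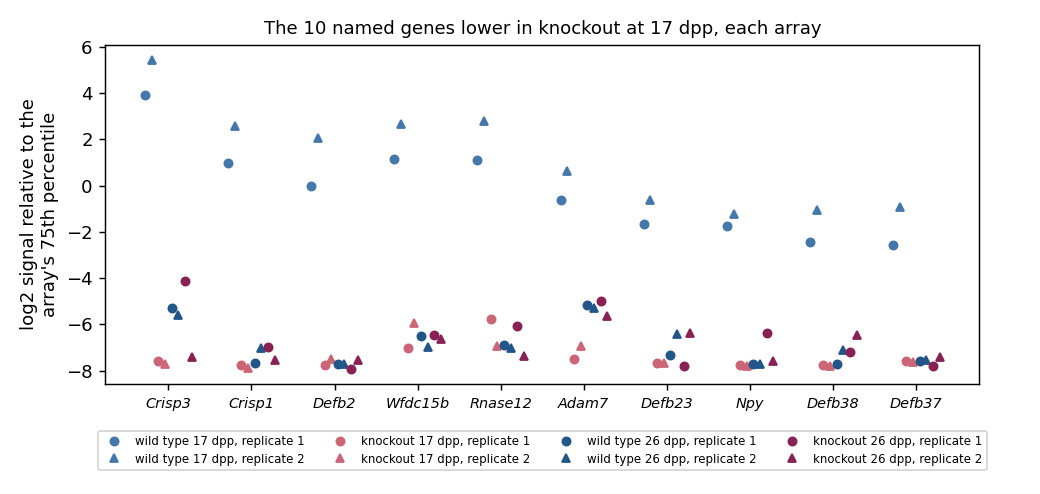
Log2 signal relative to each array's 75th percentile (vertical axis) of 10 genes lower in knockout at 17 dpp, in each of the 8 arrays; circles are replicate 1, triangles replicate 2 and colours the groups. At 17 dpp Crisp3 reads 4.66 on average in wild type and −7.65 in knockout, and Crisp1 reads 1.77 and −7.81.

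Limma called 24 of 26584 genes at 17 dpp, 23 lower and 1 higher, the latter a transcript named only by an accession (at least 3.28-fold). Of the 23, 22 were not well above background on both knockout arrays at 17 dpp, and 22 not on both wild type arrays at 26 dpp. Without wild type replicate 1 at 17 dpp 13 genes were called, 8 of them among the 24, and without either knockout array at 26 dpp 28, with 18 shared. Leaving out wild type replicate 2, knockout replicate 1 or knockout replicate 2 at 17 dpp, or wild type replicate 1 or 2 at 26 dpp, left 0 genes in limma, with 259, 537, 559, 299 and 299 at an unadjusted p under 0.05. With all arrays, limma called 1 gene with normexp and quantile normalization, 2 with normexp and the 75th percentile and 8 without a filter on dim probes. It called 0 with a variance trend, from the 4 arrays of this age alone, with the replicate number as a block and with probes well above background on all arrays (301, 999, 338 and 141 at an unadjusted p under 0.05).

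Among the fixed lists, 3 of 24 fell in knockout at 17 dpp. Epididymis markers had a median of −2.59 (−1.61 with dim genes at their bound; camera adjusted p = 7.95e-33, and adjusted p = 0.026 with an estimated correlation). Of its 14 measured members 3 fell, 7 when adjusted over the list alone, and 0 are in another list. The array medians of this list were −0.56 and 0.07 in wild type at 17 dpp, −5.73 and −6.48 in knockout at 17 dpp, −4.21 and −4.26 in wild type at 26 dpp, and −4.07 and −5.70 in knockout at 26 dpp. The median difference ranged from −2.63 to −0.51 under 3 other scalings. Adipocyte markers had a median of −2.73 (adjusted p = 3.41e-10, and adjusted p = 0.371 with an estimated correlation), with 0 of 12 members passed. In that list Cfd, which encodes adipsin, differed by −7.65 (SE 2.251, adjusted p = 1), with 1 of 2 knockout arrays well above background. The wild type replicates lay apart on it, with medians of −1.84 and 1.84 around their mean, and the median was −0.73 without wild type replicate 2 and −4.73 without replicate 1 at 17 dpp. The list of peritubular myoid cell markers had a median of −0.23 (adjusted p = 0.00161, and adjusted p = 0.782 with an estimated correlation), with 12 of 13 members below 0. Its smooth muscle gene Cnn1 differed by −0.81 (adjusted p = 1). Over the alternatives the adjusted p of this list ranged from 0.000154 to 0.991, and the call was lost without wild type replicate 2 (adjusted p = 0.198) and without knockout replicate 2 (adjusted p = 0.304) at 17 dpp. Germ cell lists had a median of −0.08 for pachytene and diplotene genes (adjusted p = 0.976), 0.13 for round spermatid genes (0.674), 0.21 for elongating spermatid genes (0.572), 0.03 for chromatoid body genes (0.572), 0.21 for spermatogonia markers (0.125) and 0.07 for early meiotic genes (0.572). With dim genes at their bound the medians were 0.026 for round and 0.001 for elongating spermatid genes. None of these germ cell lists passed at this age. Single arrays changed this: pachytene and chromatoid body genes passed upward without knockout replicate 1 at 17 dpp (adjusted p = 2.33e-08 and 0.000132) and downward without replicate 2 (1.11e-09 and 0.0319), and early meiotic (0.00155), round (0.0256) and elongating spermatid genes (0.035) passed upward without replicate 1. Upward calls were also made for spermatogonia markers without knockout replicate 2 at 17 dpp (0.0319), and for elongating spermatid genes (0.0124) and spermatogonia markers (0.034) without either knockout array at 26 dpp. Of the somatic lists, Sertoli (0.00442), matrix (0.00196) and macrophage lists (0.00177) passed downward without knockout replicate 1 at 17 dpp, as did endothelial (0.000882), matrix (0.0146) and macrophage lists (0.00708) without wild type replicate 1, and red blood cell genes passed upward without knockout replicate 2 (0.00638).

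At 26 dpp, 2 dim genes were lower in knockout. Adgrg7 (chromosome 16, 56732925 to 56732984), an adhesion G protein-coupled receptor, and Gal3st3 (chromosome 19, 5308348 to 5308407), a sulfotransferase, were at least 3.61-fold and at least 3.44-fold lower (adjusted p = 0.0341 each). Among the 4 groups, both were well above background only in wild type at 26 dpp. Limma called no other gene, with 653 at an unadjusted p under 0.05, fewer than a share of 0.05 of all genes. Leaving out knockout replicate 2 gave 10 genes, 3 higher and 7 lower, and leaving out knockout replicate 1 gave 12011, both sets including Adgrg7 and Gal3st3. Without any 1 of the other 6 arrays limma called 0, with 294 to 669 at an unadjusted p under 0.05. Both calls were also lost with normexp under either scaling, a variance trend, array weights, the replicate number as a block and the 4 arrays of this age alone, where limma called 0 (209 to 532 at an unadjusted p under 0.05).

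Spermatid genes had lower values in the knockout group at 26 dpp, through replicate 2. The round spermatid and acrosome genes had a median of −3.11 and the list of elongating spermatid, chromatin condensation and tail genes −4.21 (camera adjusted p = 4.32e-10 each, and adjusted p = 0.693 each with an estimated correlation). Tnp1, a transition protein of spermatid chromatin, differed by −5.04 (SE 2.687, adjusted p = 0.535), Tssk1, a testis-specific serine kinase, by −3.10, and Catsper4, a sperm calcium channel subunit, by −2.50. Without knockout replicate 2 the medians were −0.08 (adjusted p = 0.786) and −0.10 (adjusted p = 0.577). Over the alternatives the adjusted p ranged from 2.75e-16 to 0.786 for the round spermatid list and from 8.39e-17 to 0.693 for the elongating spermatid list. Pachytene and diplotene genes (median −0.64, adjusted p = 0.00178), macrophage markers (−0.64, 0.000205) and Leydig cell genes (−0.70, 0.0265) were also lower. Their members included H2-Ab1, a class II antigen-presenting protein, at −1.57 (SE 0.399), Ptprc, the leukocyte antigen CD45, at −1.01, and Hsd17b3, an enzyme of testosterone synthesis, at −1.56. Spermatogonia markers (0.84, 0.00562), cell junction genes (0.43, 0.00682), Sertoli cell markers (0.40, 0.0129) and immediate early genes (0.35, 0.0408) were higher. With an estimated correlation each of these 7 lists also had an adjusted p of 0.693. The immediate early genes did not pass under any of 3 other scalings (largest adjusted p = 0.0678). In each of these 9 lists 0 members passed over all genes or adjusted over the list alone. Without knockout replicate 2, 0 of the 9 passed. In that fit 1 list did, cholesterol biosynthesis, with a median of −0.18 (adjusted p = 0.00633).

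**Figure D3:**
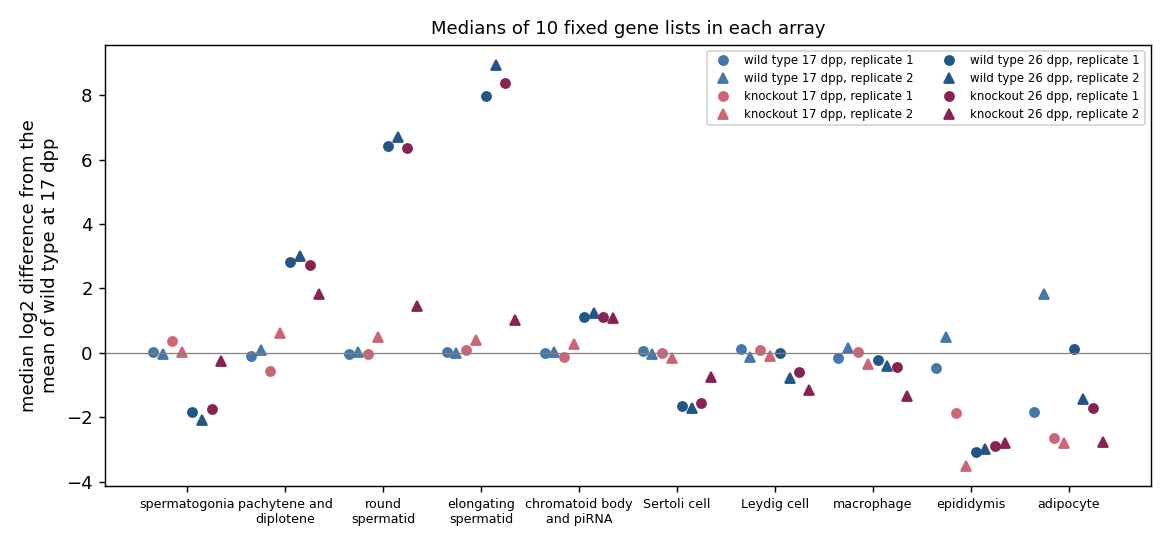
Median log2 difference from the wild type mean at 17 dpp (vertical axis) of the members of 10 gene lists in each of the 8 arrays; circles are replicate 1, triangles replicate 2 and colours the groups. Knockout replicate 2 at 26 dpp lies at 1.46 for round spermatid and 1.01 for elongating spermatid genes, where the other 26 dpp arrays lie at 6.37 to 6.70 and 7.98 to 8.95.

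Averaged over both ages, Defb40 had the smallest adjusted p of the knockout effect, 0.0894, and Crisp1, Adgrg7, Gal3st3 and Amigo3 were among the genes that followed at 0.156. Defb40 was well above background only in wild type at 17 dpp, so no size is given for its average. Limma thus called 0 genes, with 573 at an unadjusted p under 0.05, fewer than a share of 0.05 of all genes. Leaving out knockout replicate 2 at 26 dpp let 2 genes pass, Defb40 (adjusted p = 0.0425) and an unnamed lincRNA. The count was 7841 without knockout replicate 1 at 26 dpp and 3 without wild type replicate 1 at 17 dpp. Of the lists 11 passed, 4 higher and 7 lower. Epididymis markers fell (adjusted p = 4.66e-14, and adjusted p = 0.129 with an estimated correlation), with 7 members lower when adjusted over the list alone and 0 over all genes. Adipocyte markers (7.89e-06), macrophage markers (median −0.39, 7.89e-06), round spermatid (−1.37, 3.01e-07), elongating spermatid (−1.81, 4e-07), pachytene and diplotene (0.00312) and Leydig cell genes (0.032) fell as well (adjusted p = 0.707 each with an estimated correlation). Spermatogonia markers (0.51, 0.000502), cell junction genes (0.0212), early meiotic genes (0.0289) and homologous recombination genes (0.0289) rose (adjusted p = 0.707 each with an estimated correlation). None of these 10 lists had a member that passed. Early meiotic genes passed under 2 of 3 other scalings (largest camera adjusted p = 0.0545). When knockout replicate 2 at 26 dpp was left out, the median shrank to −0.11 for macrophage markers and to 0.17 for spermatogonia markers. Round and elongating spermatid genes were then at 0.049 each, and epididymis and adipocyte markers at −1.31 and −2.23.

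The knockout effect differed between ages for 0 genes in limma, with 504 at an unadjusted p under 0.05, fewer than a share of 0.05 of all genes. Defb40 again had the smallest adjusted p, 0.0999. Leaving out knockout replicate 2 at 26 dpp let Defb40 and Npy pass, each with an adjusted p of 0.0493; among the groups both were well above background only in wild type at 17 dpp, so the sizes are not given. The count was 8643 without knockout replicate 1 at 26 dpp and 3 without wild type replicate 1 at 17 dpp. Across the 26584 genes, which are not independent replicates, the knockout effects at 17 and 26 dpp had r = −0.05 and rho = −0.10. Of 9 ways to split the arrays into pairs within each age, the others gave an absolute r of up to 0.12. The sign of r turned without knockout replicate 2 at 17 dpp (0.0287) and without knockout replicate 2 at 26 dpp (0.0909).

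In wild type, spermatid genes rose from 17 to 26 dpp. Hils1 and H1f7, histone H1 variants of spermatids, were at least 4270-fold (adjusted p = 0.0178) and at least 3710-fold higher. Smcp, a protein of the sperm mitochondrial sheath, was at least 2960-fold higher, Ropn1, a sperm tail protein, at least 1970-fold, and Spaca3, an acrosomal protein, at least 1660-fold (adjusted p = 0.0168). Scp2d1, Tmco5, Gtsf1l and Spata46, in none of the fixed lists, were at least 3200-, 2060-, 1860- and 1770-fold higher. Of 38 round spermatid genes 35 rose, all 38 when adjusted over the list alone, with a mean of 6.94 (median 6.32 with dim genes at their bound; camera adjusted p = 5.55e-14, and adjusted p = 0.516 with an estimated correlation). Of 37 elongating spermatid genes 36 rose, all 37 when adjusted over the list alone, with a median of 8.43 (7.98 with bounds; adjusted p = 2.25e-13, and adjusted p = 0.516 with an estimated correlation). Of 29 pachytene and diplotene genes 25 rose and 1 fell (26 and 1 adjusted over the list alone; median 2.85, adjusted p = 7.47e-11, and adjusted p = 0.516 with an estimated correlation). Among them Pgk2, the germ cell form of a glycolytic kinase, rose by 9.28 (SE 1.185, adjusted p = 0.00763), Ccna1, the cyclin of male meiosis, by 8.09 (SE 0.73, adjusted p = 0.00531) and Adam3, a sperm surface protein, by 10.69 (SE 1.989). Of 29 chromatoid body and piRNA genes 15 rose and 3 fell (17 and 3 adjusted over the list alone; median 1.16, adjusted p = 0.000827, and adjusted p = 0.516 with an estimated correlation). Tdrd6, a component of that body, rose by 8.13 (SE 1.332) and Piwil1, a piRNA-binding protein, by 4.04. With an estimated correlation 0 of the 24 lists passed; fry gave at most 0.0217 for each of these 4.

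Several somatic lists and the spermatogonia markers were lower at 26 dpp, relative to each array's 75th percentile. In whole testes such values also depend on the mix of cells. A fall in this and the next paragraph therefore does not show less of a transcript per cell, which was not tested. The median over all genes was −0.46, against which list medians are to be read. It was −0.54 with quantile normalization, −0.28 and −0.36 with normexp and quantile or 75th percentile scaling, and −0.51 in the deposited values. Of 36 Sertoli cell markers 25 fell, 28 when adjusted over the list alone (median −1.66, adjusted p = 2.2e-05, and adjusted p = 0.516 with an estimated correlation). Amh, the anti-Müllerian hormone, was at −2.26 (SE 0.319, adjusted p = 0.00862), Gdnf, a factor that maintains spermatogonial stem cells, at −2.58 (SE 0.256) and the keratin Krt18 at −4.00 (SE 0.763). Of 22 spermatogonia markers 1 rose and 12 fell (1 and 14 adjusted over the list alone; median −1.91, adjusted p = 0.0188, and adjusted p = 0.617 with an estimated correlation). The GDNF receptor Ret (−3.19) and the transcription factor Sall4 (−2.98) fell, where Ret, like Amh, was well above background on 1 of 2 arrays at 26 dpp, and Dmrtb1, a regulator of the entry into meiosis, rose by 4.12. Of 41 extracellular matrix genes 29 fell, the same number adjusted over the list alone (median −1.52, adjusted p = 1.61e-05, and adjusted p = 0.516 with an estimated correlation), among them Fn1 at −2.37 and Lamb1 at −2.33. Of 48 cell junction genes 2 rose and 32 fell (2 and 37 adjusted over the list alone; median −1.53, adjusted p = 7.96e-05, and adjusted p = 0.517 with an estimated correlation). Cdh1, E-cadherin, was at least 22.3-fold lower and Cxadr at −3.34, while Nectin3, a cell adhesion protein, rose by 3.68.

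Endothelial, peritubular myoid and red blood cell lists fell too. Of 15 endothelial markers 13 fell, also adjusted over the list alone (median −1.32, adjusted p = 0.00398, and adjusted p = 0.517 with an estimated correlation), with Robo4 at −2.17 and Cdh5 at −2.03. Of 13 peritubular myoid markers 10 fell, 11 adjusted over the list alone (−1.36, adjusted p = 0.0147, and adjusted p = 0.516 with an estimated correlation), with Acta2 at −1.53 and Tagln at −1.52. Of 12 red blood cell genes 1 rose and 8 fell, also adjusted over the list alone (−1.64, adjusted p = 0.0288, and adjusted p = 0.517 with an estimated correlation), with the globin Hba-a2 at −1.90. Of 23 immediate early and heat shock genes 1 rose and 12 fell (2 and 15 adjusted over the list alone; median −1.71, adjusted p = 0.0236, and adjusted p = 0.566 with an estimated correlation). Atf3 was at least 15.2-fold lower, Fos at −2.76 (1 of 2 arrays well above background at 26 dpp) and Egr2 at −2.43. Of 34 apoptosis and p53 genes 4 rose and 15 fell (4 and 17 adjusted over the list alone; −1.35, adjusted p = 0.0242, and adjusted p = 0.584 with an estimated correlation). The growth arrest gene Gadd45a was at −2.51 and Fasl at least 9.72-fold higher. Of 28 interferon response genes 1 rose and 12 fell (2 and 12 adjusted over the list alone; −1.17, adjusted p = 0.0492, and adjusted p = 0.516 with an estimated correlation), with Rsad2 at −2.66 (also 1 of 2) and Dhx58, a cytoplasmic RNA sensor, at 4.64. Of 14 epididymis markers 2 rose and 9 fell, also adjusted over the list alone (−3.04, −2.53 with bounds, adjusted p = 0.0161, and adjusted p = 0.516 with an estimated correlation). Of these, Crisp1 was at least 148-fold and the lipocalin Lcn5 at least 91.3-fold lower. The fall of this list rests on a high level in both wild type arrays at 17 dpp, with array medians of −0.56 and 0.07. Knockout at 17 dpp lay at −5.73 and −6.48, and wild type at 26 dpp at −4.21 and −4.26. In knockout the median change of this list with age was 0.12. Crisp3, Rnase12 and Wfdc15b, in none of the lists, were at least 1040-, 167- and 161-fold lower.

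The other 9 lists did not pass but held genes that did. Of 25 glycolysis genes 7 rose and 7 fell (7 and 11 adjusted over the list alone; adjusted p = 0.896; median −0.95, mean 0.19, test direction up). Pgam2 rose by 9.05, the glucose transporter Slc2a3 by 4.66 and the lactate dehydrogenase Ldha by 3.01 (SE 0.284). Of 32 early meiotic genes 5 rose and 7 fell (5 and 6 adjusted over the list alone; adjusted p = 0.617; median −0.32, test direction up). Spo11, which makes the breaks that start recombination, rose by 2.44 and Syce1, of the synaptonemal complex, by 2.21, while the X-linked Tex11 was at −2.26. Of 36 homologous recombination genes 3 rose and 8 fell (1 and 5 adjusted over the list alone; 0.649), with Rpa1 at 1.96 and the checkpoint kinase Atm at −2.11. Of 23 retinoic acid genes 3 rose and 10 fell (3 and 14 adjusted over the list alone; 0.168), with the retinol dehydrogenase Rdh11 at 3.77 and Cyp26b1, which degrades retinoic acid, at −2.23. Of 24 cholesterol biosynthesis genes 2 rose and 4 fell, also adjusted over the list alone (0.574), with Fdft1, squalene synthase, at 3.09 and Ebp at −1.72. Of 23 Leydig cell genes 2 rose and 8 fell, also adjusted over the list alone (0.889; median −0.35, mean 0.17, test direction down), with Hsd17b3 at 1.82 and Dlk1 at −4.76 (SE 1.008). Of 20 macrophage markers 2 rose, 1 adjusted over the list alone (0.974; median −0.32, mean 0.01, test direction up), H2-Ab1 at 2.23 and Ptprc at 1.26. Of 12 adipocyte markers 2 fell, 1 adjusted over the list alone (0.896), among them Cidea at −1.76. Of the 20 inositol phosphate kinases and phosphatases 2 rose and 5 fell, also adjusted over the list alone (0.896; median −0.15, test direction up). Nudt4, which hydrolyses inositol pyrophosphates, rose by 1.59 (SE 0.264, adjusted p = 0.0111) and Ppip5k1, a kinase that makes them, by 1.35. Nudt10 (−1.76), Impa2 (−1.75), Minpp1 (−1.64), Ippk (−1.49) and Ip6k2 (−1.13, adjusted p = 0.0264) fell, and Ip6k1 was at 0.53 (adjusted p = 0.0838).

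X-linked genes were lower as a group at 26 dpp. The median change of 1146 X-linked genes in wild type was −1.14, with 169 higher and 529 lower, against medians of −0.52 to −0.33 on the autosomes. In knockout the X-linked median was −0.75, from 2 arrays at 26 dpp that differed. Relative to wild type at 17 dpp, replicate 1 lay at −1.08 and replicate 2 at −0.32.

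**Figure D4:**
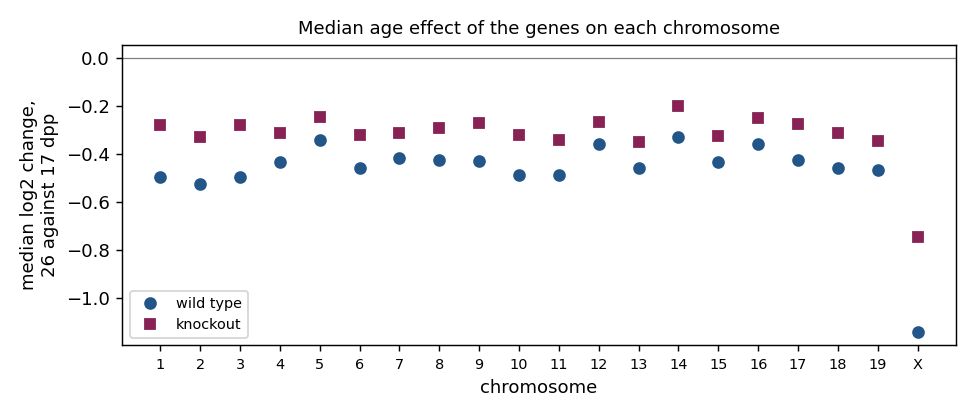
Median log2 change from 17 to 26 dpp (vertical axis) of the genes on each chromosome (horizontal axis), with circles for wild type and squares for knockout. The X chromosome lies at −1.14 in wild type and −0.75 in knockout, and the autosomes at −0.52 to −0.33 in wild type. The knockout values include replicate 2 at 26 dpp, which stood apart from replicate 1.

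Limma called 11978 genes in wild type, 5031 higher and 6947 lower. For 109 of the 3330 called genes with several kept probes, probes passed in opposite directions. The 15 lists that passed, 4 up and 11 down, kept their direction and passed with quantile normalization, with normexp and quantile scaling and in the deposited values. The number of genes depended on single arrays. It was 181 and 184 without wild type replicate 1 or 2 at 17 dpp, 152 without wild type replicate 1 at 26 dpp and 0 without wild type replicate 2 at 26 dpp (8694 at an unadjusted p under 0.05). It was 6994 without either knockout array at 17 dpp and 18364 without either at 26 dpp. In that last fit without replicate 2, 11 of the 15 lists passed, and the peritubular myoid (0.0539), epididymis (0.0738), interferon (0.0732) and red blood cell lists (0.0989) did not. Without knockout replicate 1 at 26 dpp 11 passed as well, and without wild type replicate 1 at 26 dpp 13.

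In knockout, the serine proteases Prss39 and Prss21 were at least 506-fold (adjusted p = 0.00889) and at least 217-fold higher at 26 than at 17 dpp, in a fit that includes replicate 2 at 26 dpp. Ccdc7b, Wdr88 and Slc25a54, a mitochondrial carrier, were at least 135-, 128- and 93.6-fold higher. Hrk, a pro-apoptotic protein (adjusted p = 0.0413), and Lingo2 fell, with no size given since each was well above background on 1 of 2 arrays at 26 dpp, and the keratin Krt36 was at least 4.45-fold lower. Of 29 pachytene and diplotene genes 18 rose, 23 when adjusted over the list alone (median 2.42, adjusted p = 2.76e-12, and adjusted p = 0.538 with an estimated correlation), with Pgk2 at 6.92 and Ccna1 at 6.02. Of 38 round spermatid genes 11 rose, 12 adjusted over the list alone (4.08, 3.90 with bounds, 8.58e-12), and of 37 elongating spermatid genes 8, or 9 adjusted over the list alone (4.55, 3.85 with bounds, 1.7e-10). Both spermatid lists had an adjusted p of 0.538 with an estimated correlation. Of 29 chromatoid body genes 8 rose (13 higher and 1 lower adjusted over the list alone; 0.91, adjusted p = 5.09e-05, and adjusted p = 0.538 with an estimated correlation), among them Tdrd6, well above background on 1 of 2 arrays at 17 dpp. Extracellular matrix genes (12 of 41 fell, 27 adjusted over the list alone; −1.30, 6.59e-07), Sertoli cell markers (12 of 36 fell, 13 fell and 1 rose adjusted over the list alone; −1.01, 0.00029) and cell junction genes (1 of 48 rose and 11 fell, 1 and 12 adjusted over the list alone; −1.04, 0.000239) were lower. With an estimated correlation their adjusted p was 0.538, 0.538 and 0.603. Gdnf was at −2.46, Amh at −2.35 and Sox9, a Sertoli cell transcription factor, at −1.94. Endothelial (0.000604), interferon (median −1.57, 0.00096), peritubular myoid (0.0119), red blood cell (0.0171), spermatogonia (0.0171) and immediate early lists (0.0446) were lower as well. With an estimated correlation the adjusted p was 0.538 for the first 4 of these and 0.603 for the last 2. The immediate early list passed under 2 of 3 other scalings (largest camera adjusted p = 0.0545). Without knockout replicate 2 at 26 dpp the interferon (adjusted p = 0.0583), peritubular myoid (0.205) and red blood cell lists (0.169) did not pass and apoptosis genes were lower (0.029). Without replicate 1 at 26 dpp spermatogonia markers (0.141) and immediate early genes (0.201) did not pass, and Leydig (0.000209) and macrophage lists (0.000456) passed downward and early meiotic genes (0.00712) upward. Without knockout replicate 1 at 17 dpp the red blood cell (0.0566), spermatogonia and immediate early lists (0.0609 each) did not pass, and without replicate 2 early meiotic genes passed upward (0.0108) and Leydig (0.0403) and apoptosis lists (0.0405) downward.

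Limma called 4200 genes in knockout, 2025 higher and 2175 lower, with a median over all genes of −0.31 (−0.33, −0.19, −0.24 and −0.34 under the same other scalings as in wild type). Leaving out knockout replicate 2 at 26 dpp gave 15860, among them 4193 of the 4200, and medians of 6.44 and 8.25 for round and elongating spermatid genes. It was 5056 without knockout replicate 1 at 26 dpp, 1185 without knockout replicate 2 at 17 dpp, and 0 in limma without knockout replicate 1 at 17 dpp (5589 at an unadjusted p under 0.05). Leaving out a wild type array gave 81 (either at 17 dpp) or 49 (either at 26 dpp). The age effects in wild type and knockout, which share no array, had r = 0.917 and rho = 0.867 across the 26584 genes. This r was 0.575 without knockout replicate 1 at 26 dpp. Both comparisons called 1976 genes higher and 1960 lower, where independent lists would share 383.2 and 568.4, and 4 genes had opposite directions. The lists are not independent, since both come from the same fit with a shared spread per gene, so the excess is not a test.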

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

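The tests of a mixed sample, of the stage of the animal, of macrophage markers and of epididymal tissue in this part were chosen after the results were seen, and that of array quality before; a planned stage index with Insl3 had no probe of that name, and the test was changed after the values of Hsd3b6 had been seen. The 8 lists below were picked out because their knockout effect differed between 17 and 26 dpp by camera. The knockout effect lay lower at 26 than at 17 dpp for pachytene and diplotene genes (median difference −0.48, adjusted p = 0.0134), round spermatid genes (−3.09, 7.74e-09), elongating spermatid genes (−4.47, 5.8e-09) and macrophage markers (−0.44, 0.0206), with an adjusted p of 0.803 each with an estimated correlation. It lay higher for Sertoli cell markers (0.53, 0.0032), epididymis markers (2.57, 6.99e-10), cell junction genes (0.43, 0.018) and immediate early genes (0.39, 0.0352). With an estimated correlation the adjusted p was 0.242 for epididymis markers and 0.803 for the other 3 of these. The immediate early genes passed under 2 of 3 other scalings (largest camera adjusted p = 0.058). Leaving out knockout replicate 2 at 26 dpp, 3 of the 8 passed, elongating spermatid genes (median −0.37, adjusted p = 0.0194), Sertoli cell markers (0.10, 0.0194) and epididymis markers (2.56, 7.78e-17), and so did 2 further lists, peritubular myoid markers (0.346, 0.0017) and cholesterol biosynthesis genes (−0.32, 0.0119).

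The germ cell part of this difference lay in knockout replicate 2 at 26 dpp, which had chromatoid body genes at 1.08 relative to wild type at 17 dpp, near the other 26 dpp arrays (1.12 to 1.25), and pachytene genes at 1.84 (others 2.74 or more), but elongating spermatid genes at 1.01 against 7.98 to 8.95. A mixture of RNA of both ages is argued against, since on the linear scale the array lay at 0.106% of the way from 17 to 26 dpp for elongating spermatid genes (interquartile range 0.0142 to 1.99) and at 40.6% for pachytene genes (31.9 to 56.1). So is a failed labelling or scan, since the median coefficient of variation over replicate spots was 3.96% (others 3.68 to 6.11) and the spike-in correlation 0.998 (others 0.997 to 0.999). The spike-in level, 11.025 against 9.41 to 9.88 on the other 26 dpp arrays and 10.505 to 11.02 at 17 dpp, leaves the amount and quality of this sample's own RNA untested. For spermatid genes, a lack in both knockouts as large as that in replicate 2 is argued against as well. Replicate 1 had round and elongating spermatid medians of −0.084 and −0.098 relative to wild type at 26 dpp. The wild type arrays lay at −0.233 and 0.233 and at −0.524 and 0.524. On the linear scale replicate 1 lay at 94.3% and 93.4% of the way from 17 to 26 dpp for these lists. A small delay in replicate 1 cannot be told from the spread of the wild type arrays. For pachytene and diplotene genes less mature germ cells in both knockouts stay open, since replicate 1, at −0.17, lay below both wild type arrays (−0.054 and 0.054). The somatic measures cannot decide on an animal at an earlier stage, and 4 of 8 lay closer to wild type at 17 than at 26 dpp. These were Amh relative to Sertoli markers, Hsd3b6 relative to Leydig cell genes, Sertoli markers at −0.74 and junction genes at −0.525. Amh was well above background on 1 of 2 wild type arrays at 26 dpp. Hsd3b6 was not well above background in this array, and its index, −5.21, lay below all other arrays at −3.47 to −1.40. Endothelial (−1.205), myoid (−1.394), matrix (−1.093) and red blood cell lists (−1.145) lay closer to 26 dpp. List medians in whole testes also depend on the mix of cells, so a sample with fewer spermatids could lie nearer to 17 dpp at either stage. Macrophage markers, at −1.352 against −0.427 to 0.146 elsewhere, lay outside the range of the other arrays by more than its width. This is unlike either sampled age, but no age between them was sampled. The median also depends on the mix of cells and comes from 1 array, so it cannot decide on stage. For the germ cell values stage remains open, as do, untested, a wrong age label and a knockout effect strong in this animal alone.

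The epididymis part lay in both wild type arrays at 17 dpp, where of the listed markers Spink8 averaged 5.18 and Crisp1 1.77. Epididymal tissue carried over with these testes remains open. Of 14 measured markers 8 (57.1%) were higher in both of these arrays than in each other array. Of the 8, 7 (among these Lcn5, Crisp1, Adam7 and Spink8) led by more than both arrays differed and Wfdc10, bright on every array, by less. The rule asked for more than 50%, which the 8 met and the 7 did not. The size of the lead was added to it after the values were seen. A count of markers does not separate such tissue from testis cells. Adipocyte markers, which also fell in knockout at 17 dpp, lay at −1.84 and 1.84 in these arrays around their mean. On that scale they lay at −2.66 and −2.80 in knockout at 17 dpp. At 26 dpp they lay at 0.12 and −1.43 in wild type and −1.73 and −2.77 in knockout. Of the 14 epididymis markers, 7 were well above background on at least 1 wild type array at 26 dpp and 6 on at least 1 knockout array at 17 dpp, so some are also measured in testes without the high level. Expression by wild type testis cells at both ages is argued against, since the lower wild type median at 26 dpp was not above the highest knockout median (difference −0.189). Expression by testis cells that depends on Ip6k1 at 17 dpp only was not tested and remains open.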

How the results depend on the processing

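All alternatives below were planned. Of 239 gene results run under them, 218 of which had passed, 1 reversed, the average effect on Gmppb, which had not passed (range without 1 array −0.315 to 0.0268). Of the main counts and values, 185 were kept, 29 became larger or passed, 55 became smaller or no longer passed, and 3 moved. A count was kept when within a set fold of the main count, which is not a threshold of significance. A correlation was kept when within 1 SD of the fits without 1 array, and Ip6k1 when on its side of the threshold. For the genes, 2946 values stayed on their side of the threshold, 1470 no longer passed, most where an array was left out, and 20 passed anew. Counts are of genes in limma; counts at an unadjusted p under 0.05 follow each 0 in parentheses where limma gave them. Unless the construction of an alternative shows it, the cause was not tested. At 17 dpp, knockout against wild type gave 1 gene with normexp and quantile normalization, 2 with normexp and the 75th percentile, 8 without a filter on dim probes (more genes tested), 0 (141) with probes well above background on all arrays, which removes dim genes, 0 (301) with a variance trend and robust eBayes, 39 with array weights, 0 (999) from its own 4 arrays, and 302 at an unadjusted p and at least 2-fold. At 26 dpp it gave 4 with quantile normalization, 0 (360) and 0 (327) with normexp and quantile or 75th percentile scaling, 0 (345) with probes well above background on all arrays, 7 with the mean of a gene's probes, 0 (497) with a variance trend, 0 (209) with array weights, 0 (222) from its own 4 arrays, and 470 at an unadjusted p and at least 2-fold. The average and the difference between ages gave 1 gene each with quantile normalization and 266 and 479 at an unadjusted p and at least 2-fold. The age effect in wild type gave 19798 with array weights and 18652 from its own 4 arrays, and in knockout 60, 0 (5279) and, at an unadjusted p and at least 2-fold, 7340. Lists that passed numbered 8 for age in wild type with probes well above background on all arrays, where epididymis markers had no value. With an estimated correlation 1 list passed at 17 dpp, 0 at 26 dpp, 0 in the average, 0 in the difference between ages and 0 for age in wild type and in knockout; fry gave 1 at 17 dpp, 0 at 26 dpp, 1 in the average and 1 in the difference.

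Leaving out 1 array leaves a group with a lone sample, which is assumed to vary like the other groups. Counts then ranged over 0 to 28 genes at 17 dpp, 0 to 12011 at 26 dpp, 0 to 7841 in the average, 0 to 8643 in the difference, 0 to 18364 for age in wild type and 0 to 15860 in knockout. The lists that passed ranged over 2 to 11, 1 to 13, 4 to 13 and 5 to 10 in the first 4 of these. Ip6k1 ranged over −0.88 to −0.76 at 17 dpp and −1.48 to −1.37 at 26 dpp, the correlation of knockout effects over −0.117 to 0.0909 and that of age effects over 0.575 to 0.970. With the replicate number as a block, which the labels do not tie to a shared animal, litter or day, knockout against wild type gave 0 genes at 17 dpp (338 at an unadjusted p under 0.05) and 0 at 26 dpp (532), and age 960 in knockout and 8795 in wild type. Deviations of same-numbered arrays correlated across genes at −0.401 to 0.11 over the 6 pairs of groups. With 1 deviation per group, and genes that are not replicates, this cannot decide whether same-numbered arrays share a litter or day. Signal over background limits the genes called at 17 dpp, most of which had only a bound in knockout.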

Other observations

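The tests of the flank of Ip6k1, of other splits of the arrays and of the X chromosome in this part were chosen before the results were seen, and the test of the flank without knockout replicate 2 at 26 dpp and the division of the flank at 1 Mb after. Of 3411 long non-coding RNA probes, 327 rose and 615 fell with age in wild type (9.59% and 18%), and of 18192 genes with a symbol 3766 rose and 5325 fell (20.7% and 29.3%), a difference in frequency that was not tested. Of 226 genes named as vomeronasal or olfactory receptors, which serve chemosensation, 30 rose and 22 fell.

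Among genes with an unadjusted p under 0.05 and the same sign of the knockout effect at both ages, 2 of 24 lay within 20 Mb of Ip6k1 with all 8 arrays, against 0.44 expected. Both lay within 1 Mb. This share did not pass (odds ratio 4.88, 95% interval 0.554 to 19.9, Fisher's exact p = 0.0712). Without knockout replicate 2 at 26 dpp it was 5 of 57 against 1.05 expected (5.19, 1.61 to 13, exact p = 0.0039). Sequence of another strain linked to the allele remains open for such genes, as does an effect of the allele on its neighbours, and these were not separated: 3 of the 5 (Amigo3, Hyal3 and Hyal1) lay within 1 Mb, and 2 (Chst2 and 1300017J02Rik) at 1 to 20 Mb against 0.892 expected.

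For the average knockout effect the real split of the arrays into 4 and 4, with age in the model, called 0 genes in limma (573 at an unadjusted p under 0.05), so that each of the 34 splits called as many by necessity and their count says nothing about chance; the highest other called 26. The split by age itself called 15929 without age in the model, which shows the structure of the samples by age. For chromosomes, the median change of X-linked genes with age in wild type, −1.14, lay below that of every autosome. Knockout replicate 1 at 26 dpp had an X-linked median of −1.08 relative to wild type at 17 dpp and replicate 2 −0.32. Silencing of the X chromosome in spermatocytes is a candidate explanation that was not tested separately from the changing mix of cells.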
